A study of Homo sapiens and Mus musculus with 12 samples.

How the data were processed

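The series holds 12 RNA sequencing libraries from polysome profiling, in which cell lysate is spun through a sucrose gradient so that mRNAs sediment by the number of ribosomes they carry. A375 is a human melanoma cell line and Yumm1.7 is a mouse melanoma cell line. Per the series description, each line was profiled as parental cells and as drug-tolerant persister cells, which are cells that survive a drug without being stably resistant. The labels name the 2 states of each line P and S and do not say which letter stands for which cells, so the states are called P and S throughout. Every difference is given as S relative to P. Each state of each line gave 1 input library, from RNA before the gradient. It also gave 1 monosome library (the single-ribosome peak with several lighter fractions before it) and 1 polysome library (the densest fractions at the bottom).

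Per the labels' protocols, RNA was extracted with a phenol reagent for liquids, mRNA was selected with poly-T beads, and libraries were made by random priming and PCR. The deposited values are TPM (read density of a gene scaled so that all genes of a library sum to 1000000), in 1 table per cell line, made by the authors from their reads. Per the submitters' processing notes, the genome builds were GRCh38 (hg38) for human and GRCm38 (mm10) for mouse. The aligner, the quantifier, their versions, the annotation release and the strand setting are not given in the sources used here. The smallest mean over the 6 libraries is 0.1 TPM in both tables, so genes below about that level are not listed. The tables list 16782 genes for A375 and 12711 for Yumm1.7. The deposited TPM of the listed genes sums to between 66.6% and 90.2% of 1000000 in the A375 libraries and between 84.5% and 94.4% in the Yumm1.7 libraries.

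TPM keeps no read depth, so the depth of each library is unknown and no counting error could be given. TPM is also relative within a library: it says which mRNAs make up a fraction and nothing about how much RNA or how many ribosomes the fraction held. Reads from genes with near-identical copies or pseudogenes, ribosomal protein genes and histones among them, and from overlapping genes can be split differently between copies by the authors' quantification, so single members of these families are less certain than the family.

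Values were compared as log2(TPM + 1). Genes with a mean of at least 1 TPM over the 6 libraries of their line entered the comparisons (12638 genes in A375 and 10492 in Yumm1.7), and a difference of at least 2-fold on this scale was counted. A log2 difference on this scale understates the difference of low genes. For each line, S was compared with P in the input libraries, the polysome library was compared with the monosome library within each state, and the log2 polysome-to-monosome ratio of S was compared with that of P. Each group has 1 library. No statistical test across replicates was therefore planned or made, no p-value or standard error is given, and no difference has a replicate check.

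The median gene itself differed between libraries. The median log2 value over the genes tested was -0.20 in A375 and -0.94 in Yumm1.7 for S against P in input, and -0.29 and -1.42 for the difference of the polysome-to-monosome ratio. Gene and list values in the text are therefore given relative to the median gene, a choice made after the data were seen, and counts are given both as deposited and relative to the median gene.

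The 40 gene lists (cell cycle, translation machinery, stress responses, melanoma states, metabolism, markers of other cell types) were fixed before the data were examined. For each list, the median of its members was placed among the medians of 10000 random lists of the same size, matched on mean TPM in 20 bins. A percentile below 2.5 or above 97.5 is treated as standing apart. These percentiles describe these libraries and are not tests across replicates. Older gene symbols in the tables (58 in Yumm1.7 and 2 in A375) were matched to list members after the tables were seen. The lists of keratinocyte, leukocyte and endothelial markers had fewer than 3 members tested in either line and gave no value. The list of cytosolic ribosomal proteins holds 80 genes, all of which are in the Yumm1.7 table, whereas 6 of them were analysed in A375 and the other A375 ribosomal protein genes are not analysed here and do not enter the A375 TPM sums and shares.

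Genes were named by a rule fixed before the data were examined: the 8 highest and 8 lowest genes with a mean of at least 10 TPM (5 each for ratios within a state), up to 4 members of each list with the largest values and a mean of at least 5 TPM, the 10 genes highest and the 10 lowest in both lines, and a fixed set of melanoma, translation and ribosome synthesis genes. The values of 1 gene that the rule covers are not reported here. Other genes are marked where they were chosen after their values were seen. Genes of the 2 lines were matched by symbol in capital letters (8521 genes). Positions of A375 genes are from the RefSeq annotation of GRCh38, in which 16343 of the A375 symbols were found. No mouse annotation was used. Coding lengths are the longest annotated coding sequence of the human gene of the same symbol in GENCODE. They were used in a test chosen after the results were seen and in a correlation across genes.

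The calculation was tested on simulated libraries built from the real input TPM with 200 changed genes and noise of 0.3 on the log2 scale. In the A375 simulation of 12638 genes, 97.2% of genes changed by 4-fold and 37.3% of those changed by 2-fold were counted, with 1% of unchanged genes. In the Yumm1.7 simulation of 10492 genes, the values were 87.5%, 49.3% and 1.01%. The noise level was assumed, far fewer genes were changed than in the data, and only S against P in input was scored. The values check the calculation and are not error rates of the real comparisons. Alternatives covered the pseudocount, the filter on low values, the scaling, the genes left in the TPM total, the fold threshold and the libraries compared. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.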

Results

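Polysome profiling libraries were compared for 2 melanoma cell lines, human A375 and mouse Yumm1.7, each in a state labelled P and a state labelled S. Each state gave 1 input, 1 monosome and 1 polysome library, so the 12 libraries have no replicates. No difference below could be set against a spread between replicates. The depth of the libraries is unknown because the values are TPM. Libraries of one state and line had a Pearson r across genes of 0.80 to 0.95 in A375 P and 0.85 to 0.93 in A375 S. In Yumm1.7 it was 0.89 to 0.96 in P and 0.92 to 0.95 in S. P and S input libraries had an r of 0.82 in A375 and 0.77 in Yumm1.7.

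The mRNAs of the mitochondrial genome, which are translated by mitochondrial ribosomes inside mitochondria, were spread over the gradient differently in P and S. In P, they made up 23.7% of TPM in the A375 monosome library and 1.87% in the polysome library, and 13.4% and 1.74% in the Yumm1.7 libraries. In S, the shares were 6.55% in monosomes and 5.70% in polysomes in A375, and 19.0% and 18.4% in Yumm1.7. In input RNA they went from 9.30% in P to 12.2% in S in A375 and from 8.76% to 17.0% in Yumm1.7. Cytosolic ribosomal protein mRNAs of Yumm1.7 made up 29.8% of the P monosome library and 15.4% of the P polysome library, against 15.8% and 15.7% in S. Mitochondrial ribosomal RNA took 24.8% of TPM in the A375 S monosome library and 2.06% in the P monosome library, with MT-RNR2, named after its value was seen, at 156090 TPM in S.

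**Figure D1:**
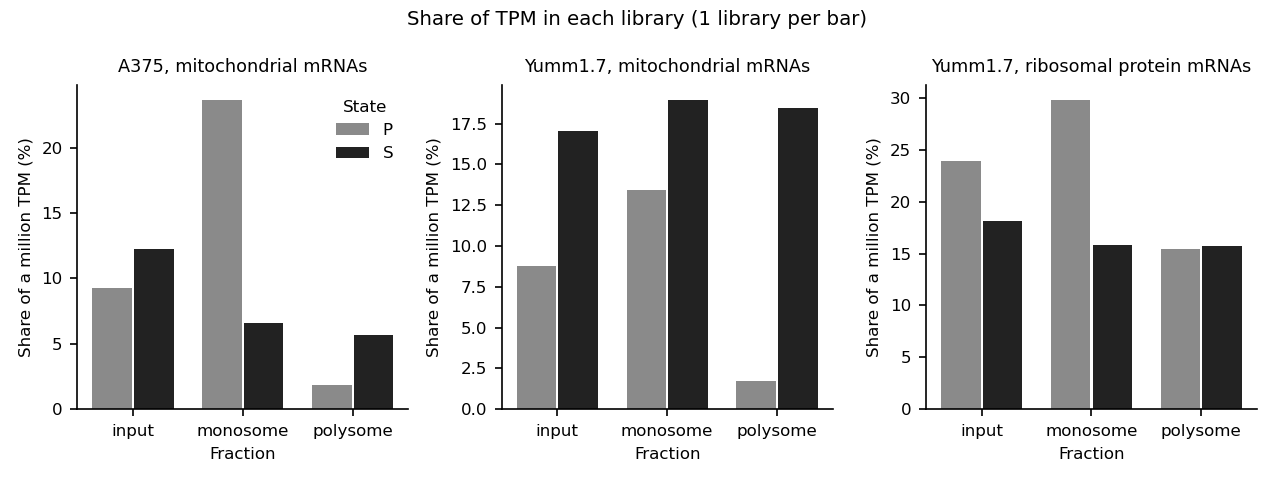
Share of TPM (vertical axis, percent) taken by mitochondrially encoded mRNAs in A375 and Yumm1.7 and by cytosolic ribosomal protein mRNAs in Yumm1.7, in the input, monosome and polysome library of states P (grey) and S (black), 1 library per bar. Mitochondrial mRNAs took 1.87% and 1.74% of the P polysome libraries and 5.70% and 18.4% of the S polysome libraries.

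The comparison of input RNA asked how the mRNA content of the cells differed between S and P. In A375, proliferation genes were far lower in S. All 30 genes of the G2/M list (median log2 -4.32 relative to the median gene, percentile 0) and all 30 of the G1/S list (-2.75, percentile 0) were at least 2-fold lower. CDC20, which activates the anaphase-promoting complex (chromosome 1, 43358981 to 43363203 in GRCh38), went from 352 to 3.21 TPM. The ubiquitin-conjugating enzyme UBE2C went from 248 to 2.72, the mitotic kinase PLK1 from 101 to 0.878, the replication factor CDC45 from 76.0 to 0.322 and the thymidylate synthase TYMS from 530 to 9.14. Output genes of the MAPK pathway, which drives growth in melanomas with mutant BRAF, were lower too (15 of 20 members at least 2-fold lower and 1 higher, median -1.85, percentile 0). SPRY4 had 139 TPM in P and 0.987 in S, ETV4 177 and 4.82, DUSP6 115 and 3.72 and MYC 37.5 and 1.80. The highest gene in S relative to P was NGFR, the nerve growth factor receptor used as a marker of neural crest-like melanoma cells (chromosome 17, 49495293 to 49515008 in GRCh38, 0.418 TPM in P and 757 in S). It was followed by TMEM59L (0.419 and 148), ANGPTL7 (0.166 and 95.2), the matricellular protein gene CCN3 (46.3 and 3334) and the lysosomal membrane gene CD68 (5.76 and 420). The others among the 8 highest were CRYGS (3.35 and 260), the chemokine gene CXCL14 (listed at 0 in P and 50.7 in S) and SEMA3C (6.24 and 327). HAPLN1 (97.3 and 0.224) and SPRR2D (78.0 and listed at 0) were also among the 8 lowest.

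Some but not all lists of protein synthesis genes were lower in A375 S input RNA. Those that did not stand apart were the 4 large-subunit ribosomal proteins analysed (median 0.47, percentile 76.37) and 28 mitochondrial ribosomal proteins (-0.38, percentile 6.64). Nor did other mRNAs with a 5-prime terminal oligopyrimidine tract, described below (0.30, percentile 83.14). Of 71 ribosome biogenesis factors, 45 were at least 2-fold lower and none at least 2-fold higher (median -1.25, percentile 0), led by the pseudouridine synthase DKC1 (227 TPM in P and 26.5 in S), nucleolin NCL (851 and 116, but higher in S in the monosome libraries) and NOP56 (477 and 82.0). Cytosolic tRNA synthetases (12 of 20 lower, median -1.04, percentile 0.01), translation initiation factors (7 of 30 lower, median -0.78, percentile 0.1, with EIF5A at 2224 and 421 TPM) and RNA polymerase I components (4 of 15 lower, median -0.64, percentile 2.26) pointed the same way. So did targets of the stress transcription factor ATF4 (17 of 25 lower and 1 higher, median -1.69, percentile 0). Among them were the serine synthesis gene PSAT1 (187 and 13.2 TPM) and the mitochondrial folate enzyme gene MTHFD2 (205 and 17.9). ATF3 of this list was higher (7.76 and 128). Cytosolic heat shock proteins and chaperonins (median -1.17, percentile 0), nuclear noncoding RNAs (-1.75, percentile 0.32), proteasome subunits (-0.66, percentile 0.33), cholesterol synthesis genes (-0.65, percentile 0.53) and glycolysis genes (-0.60, percentile 1.86) also stood low. The lactate dehydrogenase gene LDHA had 2470 TPM in P and 450 in S. In the monosome libraries, 7 of these lists did not stand low: proteasome subunits (percentile 33.51), nuclear noncoding RNAs (63.07), initiation factors (30.96), tRNA synthetases (20.76), heat shock proteins (17.83), glycolysis (17.79) and RNA polymerase I components (2.85). In the polysome libraries, glycolysis (7.24), nuclear noncoding RNAs (35.63) and proteasome subunits (2.85) did not.

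Higher groups in A375 S input RNA were lysosome genes, class I antigen presentation, replication-dependent histones, interferon-stimulated genes and melanocyte differentiation genes. Of 31 lysosome genes, 17 were at least 2-fold higher and none lower (median 1.23, percentile 100). The cathepsin gene CTSD had 74.1 TPM in P and 834 in S, PSAP 792 and 3958 and SMPD1 9.31 and 112. Of 8 class I antigen presentation genes, 6 were higher (median 1.78, percentile 99.99), among them HLA-B (2.91 TPM in P and 26.2 in S) and B2M (1192 and 5392). Replication-dependent histone mRNAs, which normally lack a poly(A) tail, had a median of 1.66 (9 of 12 higher and 3 lower, percentile 100), with H1-2 at 20.7 and 360 TPM. Interferon-stimulated genes (7 of 18 higher and 3 lower, median 0.87, percentile 99.89) included ISG15 at 19.1 and 107 TPM and OAS3 at 10.2 and 2.25. Melanocyte differentiation genes (6 of 14 higher and 2 lower, median 0.61, percentile 98.26) included DCT at 25.2 and 249 TPM and PMEL at 6.49 and 39.5, and did not stand high in the polysome libraries (percentile 82.47). Of the fixed single genes, CCND1 (-1.39), AXL (-1.54), MALAT1 (-2.55) and EIF4E (-1.01) were lower, although MALAT1 was higher in S in the monosome and polysome libraries and AXL was not lower in the monosome libraries. MITF (-0.42), SOX10 (0.68), ATF4 (-0.89), MTOR (0.57), RRN3 (-0.75), POLR1A (-0.64) and UBTF (-0.19) were within 2-fold of the median gene. The medians of the other 17 lists tested in A375 did not stand apart from matched random lists. Among them, mitochondrial ribosomal proteins had 28 of 76 members analysed and cytosolic large-subunit ribosomal proteins 4 of 48. The list of neural crest-like and dedifferentiation genes of melanoma, which holds NGFR, was also among them (8 of 22 higher and 2 lower, median 0.18, percentile 78.26). It stood high in the monosome libraries (percentile 99.98) but not in the polysome libraries (61.25).

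In A375, 1498 genes were at least 2-fold higher and 2642 lower in S input RNA out of 12638, or 1969 and 2048 relative to the median gene. Of the latter, 789 and 800 were past 2-fold in the same direction in all 3 fractions.

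In Yumm1.7, the same lists of proliferation and growth genes were lower in S input RNA. Of 30 genes in each list, 29 were at least 2-fold lower for G2/M (median -3.39, percentile 0) and 29 for G1/S (-2.89, percentile 0), as were 17 of 18 MAPK output genes (-2.54, percentile 0). Fosl1, an AP-1 transcription factor gene downstream of MAPK signalling, had 207 TPM in P and was listed at 0 in S. Myc had 96.9 and 0.508, Etv4 81.0 and 0.372 and Dusp6 34.2 and 0.198. The other lowest genes were Birc5 (199 TPM in P), Hmgb2 (173), Csn3 (172) and Prl2c3 (130), all listed at 0 in S, and Ube2c (475 and 1.72), the matrix metalloproteinase gene Mmp3 (216 and 0.774) and Cdc20 (152 and 0.587). The S input library listed 1581 genes at 0 against 316 in P input, and in S monosomes Birc5 had 8.36 TPM and Hmgb2 5.00. Ribosome biogenesis factors (39 of 70 lower and 4 higher, median -1.15, percentile 0), with the helicase genes Ddx21 (77.7 and 2.51) and Ddx18 (44.7 and 1.46), were low as in A375. So were tRNA synthetases (9 of 20 lower, -0.87, percentile 1.57), translation initiation factors (10 of 30 lower and 1 higher, -0.78, percentile 0.4), RNA polymerase I components (7 of 15 lower and 1 higher, -0.93, percentile 2.38), ATF4 targets (14 of 26 lower and 1 higher, -1.32, percentile 0.01) and cytosolic heat shock proteins (-0.58, percentile 0.95). In the monosome libraries, tRNA synthetases (percentile 32.76), RNA polymerase I components (23.26), heat shock proteins (6.95) and initiation factors (4.73) did not stand low. In the polysome libraries, RNA polymerase I components (33.39), tRNA synthetases (6.16) and heat shock proteins (4.37) did not.

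Ribosomal protein mRNAs themselves did not share this shift in Yumm1.7 input RNA, with medians of 0.27 for the large subunit (percentile 9.39) and 0.33 for the small subunit (percentile 19.77). As a share of TPM, they were at 24.0% in P input and 18.2% in S input, and in the monosome libraries both lists stood low in S (-0.72 and -1.02, percentile 0 for both), while in the polysome libraries neither stood apart (1.44 and 1.55, percentiles 53.94 and 71.79). Other mRNAs with a 5-prime terminal oligopyrimidine tract, the motif that places translation of ribosomal proteins and elongation factors under mTORC1 control, were lower (10 of 18 lower, median -1.12, percentile 0). Npm1 had 2073 TPM in P and 119 in S and Hnrnpa1 539 and 36.1. The A375 values of this list had a median of 0.30 (percentile 83.14), with NPM1 at 3971 and 1300 TPM (not lower in the monosome libraries) but the elongation factor gene EEF1A1 at 7342 and 14543 (not higher in the polysome libraries).

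Extracellular matrix, neural crest-like and fibroblast genes were higher in Yumm1.7 S. Extracellular matrix genes (12 of 16 higher and 1 lower, median 1.99, percentile 100) included Col6a1 (0.497 TPM in P and 29.2 in S), Col3a1 (25.4 and 204) and Col1a2 (12.4 and 74.1). Neural crest-like and dedifferentiation genes of melanoma (11 of 15 higher, 1.73, percentile 99.99) included Tgfbi (0.466 and 39.3) and Sox9 (13.8 and 34.1). Fibroblast markers were higher too (4 of 5 higher, median 3.06, percentile 99.98), with Dpt at 0.926 and 35.2 TPM and Pdpn at 214 and 67.3. The 8 highest genes included Agt (0.315 and 207), the smooth muscle genes Actg2 (listed at 0 in P and 136 in S), Tagln (0.440 and 138) and Acta2 (5.97 and 603). They also included Ogn (0.964 and 238), Fstl1 (2.05 and 289), Ccn5 (0.0825 and 83.2) and Inmt (0.366 and 70.2). Lysosome genes (16 of 30 higher and 1 lower, 1.16, percentile 99.85, Ctsd at 466 and 1486 TPM) and replication-dependent histones (6 of 7 higher, 2.73, percentile 100) were higher as in A375, and lysosome genes did not stand high in the polysome libraries (percentile 70.14). Interferon-stimulated genes (13 of 25 lower and 3 higher, median -1.04, percentile 0.15) included Cxcl10 (47.5 TPM in P and listed at 0 in S) and Ifi44 (32.0 and 1.28). Antioxidant and ferroptosis genes were lower (11 of 22 lower and 5 higher, -1.03, percentile 0.19), but did not stand low in monosome (percentile 5.12) or polysome libraries (2.64). Of the fixed single genes, Ccnd1 (-4.84), Eif4e (-1.79) and Polr1a (-1.18) were lower, Malat1 (1.02, at 2.99 and 3.23 TPM) was higher. Mitf (-0.94), Axl (-0.24), Atf4 (-0.99), Mtor (-0.25), Rps6 (-0.33), Rrn3 (0.34) and Ubtf (0.51) were within 2-fold of the median gene. Sox10 and Ngfr did not reach the level needed for the comparison in Yumm1.7.

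In Yumm1.7, 938 genes were at least 2-fold higher and 5043 lower in S input RNA out of 10492, or 2422 and 2336 relative to the median gene. Of the latter, 1480 and 1224 were past 2-fold in the same direction in all 3 fractions.

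**Figure D2:**
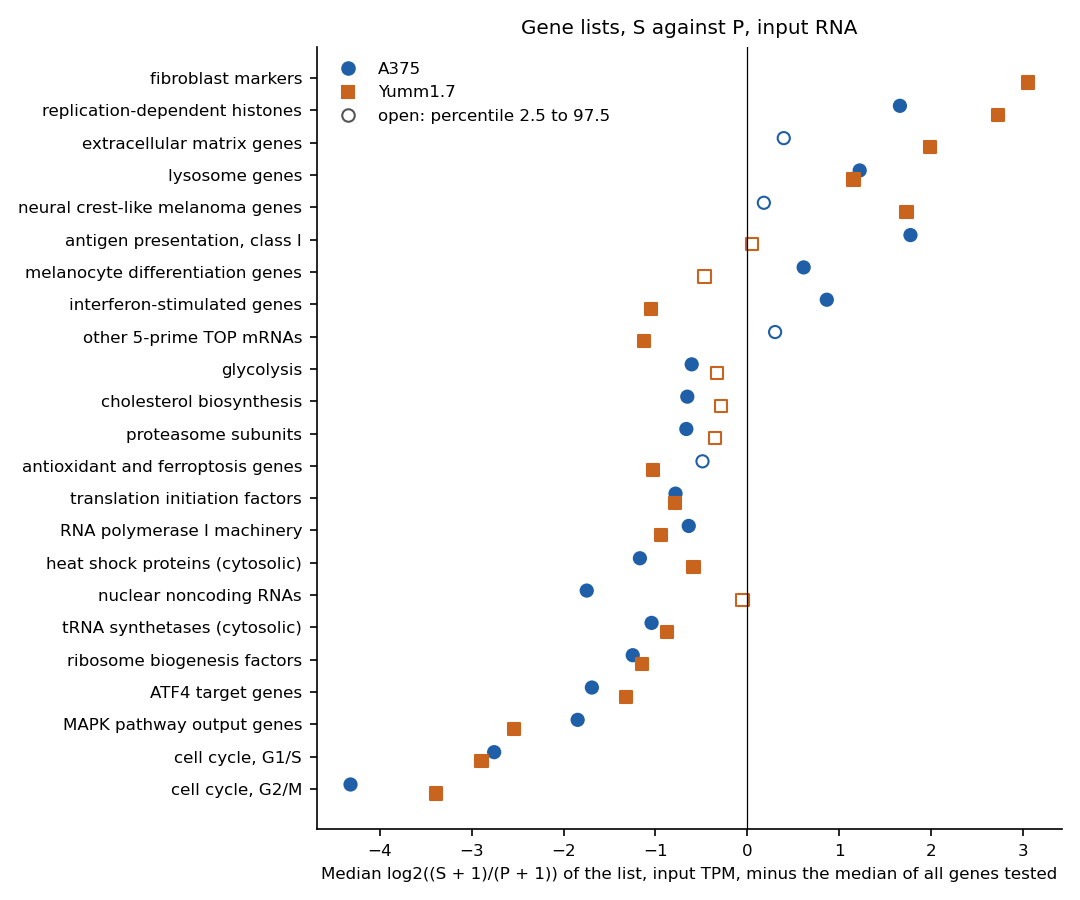
Median log2 difference of each gene list between S and P input RNA, relative to the median gene (horizontal axis), for A375 (circles) and Yumm1.7 (squares). Lists are those that stand apart from matched random lists in at least 1 line, with open symbols where the other line does not. The G2/M list stands lowest in both lines (-4.32 and -3.39).

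The S minus P differences of input RNA were compared between the 2 lines over 8521 genes with matching symbols. The differences correlated across genes (Pearson r 0.48, Spearman rho 0.43, genes not being independent replicates). Relative to the median gene, 559 genes were at least 2-fold higher in both lines, where independent lists would share 256, and 672 were lower in both, where independent lists would share 295. The genes highest in both were the small heat shock protein gene CRYAB (3.47 to 126 TPM in A375), COL8A1, TGFBI, MAF, the transglutaminase gene TGM2, SOX4, MXD4, SELENOM, COL5A2 and YPEL3, with log2 values between 3.19 and 5.72. The genes lowest in both were UBE2C, CDC20, PLK1, PBK, BIRC5, RRM2, NUF2, CCNB1, PCLAF and TOP2A, with values between -6.71 and -4.77. In the monosome libraries the correlation was lower (r 0.25), and in the polysome libraries it was 0.48.

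Polysome and monosome libraries were compared within each state to show which mRNAs sediment with many ribosomes. In P of both lines, mitochondrially encoded mRNAs and noncoding host genes of small nucleolar RNAs (snoRNAs), whose spliced RNA is poorly coding, were the least polysomal groups. The mitochondrial mRNAs had a median log2 ratio of -4.12 relative to the median gene in A375 and -3.10 in Yumm1.7 and the snoRNA host genes -4.51 and -3.20, all at percentile 0. Ribosomal protein mRNAs were less polysomal than the median gene in Yumm1.7 P (large subunit -1.57, small subunit -1.83, percentile 0 for both), as were the 4 large-subunit members analysed in A375 (-3.37, percentile 0.23), for example RPLP0 at 10081 TPM in monosomes and 1754 in polysomes. Proteasome subunits (1.99 in A375 and 1.37 in Yumm1.7, percentile 100 for both), tRNA synthetases (1.93 and 1.29, percentiles 99.99 and 100) and ribosome biogenesis factors (1.41 and 0.75, percentile 100 for both) were among the more polysomal groups in both lines. In A375, heat shock proteins (2.51, percentile 100) and glycolysis genes (2.02, percentile 100) were too. Single genes at the low end were the brain cytoplasmic RNA BCYRN1 (605 TPM in monosomes and 2.82 in polysomes) and the ferritin light chain gene FTL (12113 and 337) in A375, and mt-Rnr1 in Yumm1.7. In A375 P, 6526 genes were at least 2-fold higher in polysomes and 930 lower, or 2408 and 2634 relative to the median gene. In Yumm1.7 P the counts were 4848 and 266, or 1466 and 1401.

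In S, the mitochondrial mRNAs were nearer to the median gene (median -0.53 in A375, percentile 0.33, and 0.51 in Yumm1.7, percentile 34.48). The snoRNA host genes stayed low in A375 (-3.25, percentile 0) and less so in Yumm1.7 (-0.68, percentile 1.43). Ribosomal protein mRNAs of Yumm1.7 S were at 0.66 for both subunits (percentiles 55.34 and 55.15), while the 4 members in A375 S stayed low (-3.01, percentile 0.01). Proteasome subunits (1.98 and 1.72, percentile 100 for both), tRNA synthetases (1.33 and 0.82, percentiles 98.22 and 99.21) and ribosome biogenesis factors (1.02 and 0.41, percentiles 99.96 and 99.95) were again more polysomal. G2/M genes were less so (-1.13 at percentile 0 and -0.50 at percentile 1.07). In A375 S, 4892 genes were at least 2-fold higher in polysomes and 614 lower, or 2624 and 2114 relative to the median gene. In Yumm1.7 S the counts were 663 and 2681, or 1381 and 1142. Across genes, the ratios of S and P correlated more in A375 (r 0.74, slope of S on P 0.68) than in Yumm1.7 (r 0.36, slope 0.33), and no test of the difference was made.

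The last comparison asked whether the polysome-to-monosome ratio of an mRNA differed between S and P. In A375, all 13 mitochondrially encoded mRNAs had a ratio at least 2-fold higher in S (median 3.75, percentile 100). MT-ND1 had 7136 TPM in monosomes and 740 in polysomes of P and 3971 and 7319 in S. MT-ATP8 had 7620 and 1587 in P and 457 and 2287 in S. The snoRNA host genes (4 of 8 at least 2-fold higher, 1.07, percentile 99.77), class I antigen presentation genes (3 of 8, 0.77, percentile 98.26) and replication-dependent histones (5 of 12 higher and 2 lower, 0.59, percentile 98.19) were higher too. Of these, the mitochondrial mRNAs (1.16, percentile 100) and the histones (0.79, percentile 99.99) also stood high when polysomes were set against input. The snoRNA host genes (0.15, percentile 52.16) and class I genes (0.10, percentile 66.2) did not. Lower ratios in S were seen for G2/M genes (26 of 30 at least 2-fold lower, -2.08, percentile 0), G1/S genes (21 of 30, -1.19, percentile 0), MAPK output genes (4 of 20, -0.76, percentile 0.01) and chromatin regulators linked to persistence (5 of 14, -0.72, percentile 0.12). They were also seen for ATF4 targets (10 of 25, -0.62, percentile 0), heat shock proteins (4 of 19 lower and 1 higher, -0.56, percentile 0.09), tRNA synthetases (2 of 20, -0.52, percentile 0.08), ribosome biogenesis factors (12 of 71 lower and 3 higher, -0.44, percentile 0) and translation initiation factors (4 of 30 lower and 1 higher, -0.40, percentile 0.12). Among these 9 lists, only the MAPK output genes also stood low when polysomes were set against input (-0.33, percentile 0.45). The G2/M and G1/S lists were at 0.10 and 0.14, and ribosome biogenesis factors (0.36, percentile 100) and heat shock proteins (0.75, percentile 100) stood high. A share of P RNA in S monosomes (5.36% of P input) was estimated from cell cycle list genes at no more than 2% of P in S input. Subtracting it raises the ratio of lists that are lower in S input, as all 9 were, so the direction was largely fixed in advance. With this share subtracted, all 9 lists came nearer to the median gene, 8 of them by over 1.5 times. The G2/M list was at -1.10, G1/S at -0.46, MAPK output genes at -0.18 and ATF4 targets at -0.20. Heat shock proteins were at -0.20, tRNA synthetases at -0.15, ribosome biogenesis factors at -0.14 and initiation factors at -0.21. Chromatin regulators were at -0.58 (from -0.72). The fixed genes NGFR (2.22, with P below 1 TPM in both fractions) and DUSP6 (-1.31, but 0.82 with this share subtracted) were past 2-fold. The other 12 fixed genes analysed, ATF4 (0.50), MTOR (-0.32) and EIF4E (-0.44) among them, were within 2-fold. In all, 997 genes had a higher and 2047 a lower ratio, or 1651 and 996 relative to the median gene.

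In Yumm1.7, ribosomal protein mRNAs had higher polysome-to-monosome ratios in S. Of 48 large-subunit ribosomal protein mRNAs, 43 were at least 2-fold higher (median 2.36, percentile 100), as were all 32 of the small subunit (2.75, percentile 100). Against input the medians were 1.18 and 1.31, both at percentile 100. Rps25 had 2705 TPM in monosomes and 1716 in polysomes of P and 331 and 1548 in S. Rpl12 had 4802 and 1011 in P and 955 and 786 in S, and Rps6 had 4431 and 3108 in P and 1695 and 2636 in S. Other terminal oligopyrimidine mRNAs were higher (10 of 18, 1.37, percentile 98.23), and against input this list was at 0.86 (percentile 76.67). Tpt1 had 20956 and 3785 TPM in P and 3205 and 2046 in S. All 13 mitochondrially encoded mRNAs were higher (3.90, percentile 100, and 2.86 at percentile 100 against input). In the same order, mt-Co1 had 16240 and 4592 TPM in P and 1815 and 26575 in S. The snoRNA host genes (6 of 7, 2.73, percentile 100), nuclear-encoded oxidative phosphorylation genes (26 of 73 higher and 2 lower, 0.76, percentile 99.37), mitochondrial ribosomal proteins (24 of 76 higher and 4 lower, 0.58, percentile 100) and 5 nuclear noncoding RNAs (3 of 5, 1.60, percentile 99.54) were higher as well. Against input, the nuclear noncoding RNAs did not stand high (0.70, percentile 95.79). With monosomes set against input and the sign turned, oxidative phosphorylation genes (-0.20) and mitochondrial ribosomal proteins (-0.14) were on the other side of the median gene. Initiation factors (-0.28, percentile 24.58), tRNA synthetases (-0.57, percentile 5.3) and ribosome biogenesis factors (-0.33, percentile 16.84) did not have higher ratios.

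Lower ratios in Yumm1.7 S were seen for G2/M genes (17 of 30 at least 2-fold lower and 1 higher, median -1.21, percentile 0), chromatin regulators linked to persistence (6 of 13, -0.89, percentile 0.07) and the unfolded protein response and chaperones of the endoplasmic reticulum (7 of 22 lower and 2 higher, -0.72, percentile 0.55). The chaperone gene Hspa5 had 98.9 and 680 TPM in P and 207 and 193 in S, without a lower value against input. Lower ratios were also seen for lysosome genes (8 of 30 lower and 1 higher, -0.64, percentile 0.09), G1/S genes (10 of 30, -0.59, percentile 1.67) and genes of the mTORC1 pathway (5 of 21, -0.42, percentile 2.37). Against input, lysosome genes (-0.33, percentile 0.05) and mTORC1 pathway genes (-0.45, percentile 1.07) still stood low and chromatin regulators were at -0.39 (percentile 5.41). The G2/M, G1/S and unfolded protein response lists were at 0.14, 0.06 and 0.12. With an estimated share of P RNA (5.61% of P input) subtracted from S monosomes, the G2/M and G1/S lists were near the median gene (-0.00560 and 0.0138). The share was estimated from cell cycle list genes, so this result follows largely from the estimate and is no separate evidence for P RNA in S monosomes. The fixed genes Ubtf (-1.92), Atf4 (-1.48), Rrn3 (-1.40), Myc (-1.37) and Ccnd1 (-1.11) were lower and Mitf (1.78) and Rps6 (2.57) higher. The sign of Myc turned against input (0.60), and with the P share subtracted it turned for Myc (1.19) and Ccnd1 (0.74). Mitf was below 1 TPM in S (0.457 in monosomes and 0.429 in polysomes). In all, 315 genes had a higher and 6978 a lower ratio in S, or 1812 and 1321 relative to the median gene.

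**Figure D3:**
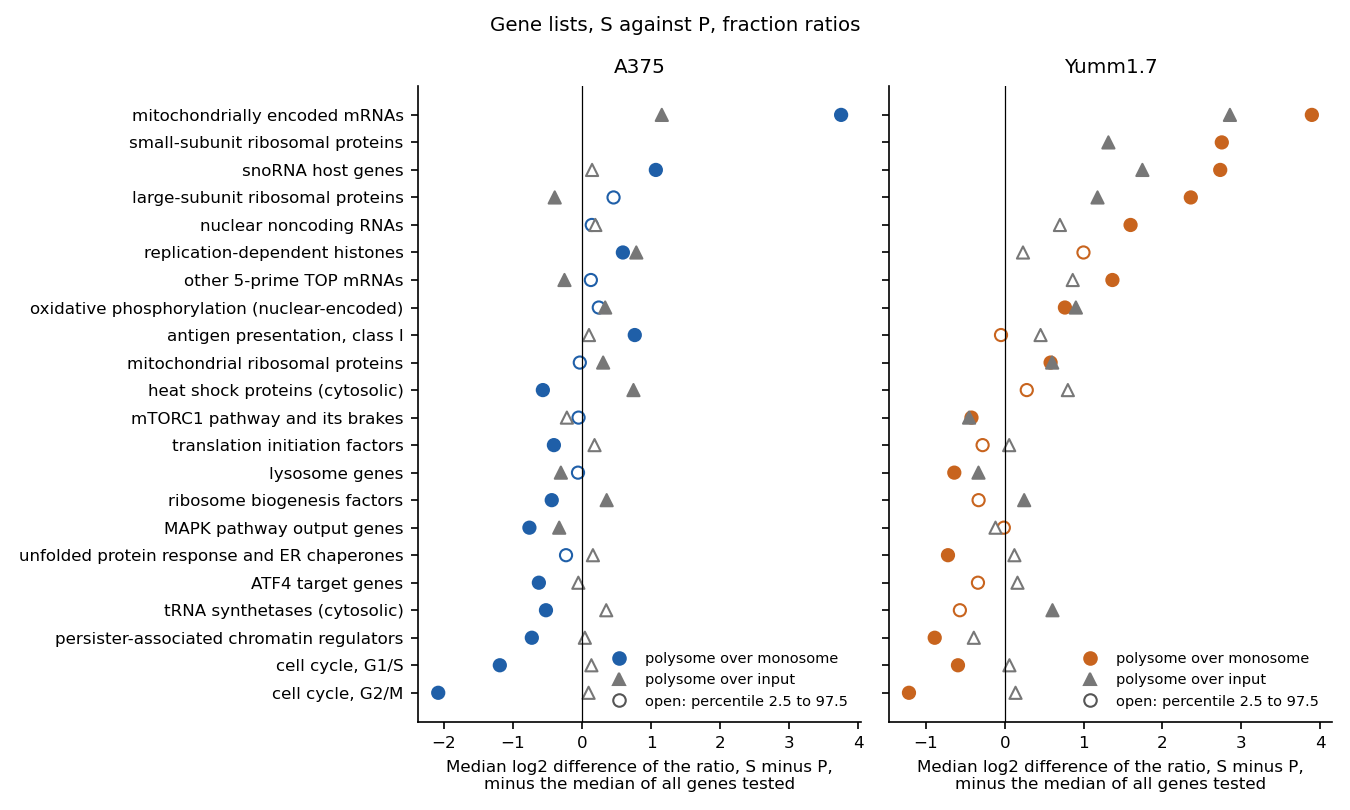
Median log2 difference between S and P, relative to the median gene (horizontal axis), of the polysome-to-monosome ratio (circles) and the polysome-to-input ratio (triangles) for gene lists in A375 (left) and Yumm1.7 (right), with open symbols for values that do not stand apart from matched random lists. Mitochondrially encoded mRNAs stand highest in both lines (3.75 and 3.90), and the cell cycle lists stand low for the ratio to monosomes and near 0 for the ratio to input.

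The low cell cycle ratios went with a feature of the S monosome libraries. Genes with at least 20 TPM in P input and no more than 2% of that in S input (a set defined after the data were seen) kept a higher share of their P input level in the S monosome library. Because the set was chosen for low S input, the choice itself favours higher values in the other S libraries. For the 14 such cell cycle genes of A375, the median level was 1.43% of P input in S input, 6.93% in S monosomes and 3.64% in S polysomes. For 32 such genes outside the cell cycle lists it was 1.25%, 4.73% and 2.13%. In Yumm1.7 the values were 0.363%, 6.21% and 0.868% for 23 cell cycle genes and 0.197%, 5.86% and 2.11% for 112 other genes. In the opposite direction, genes with at least 20 TPM in S input and no more than 2% of that in P input stood at 0.341% of their S level in the A375 P monosome library (12 genes, 1.30% in P input) and at 0.486% in that of Yumm1.7 (26 genes, 0.889% in P input).

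**Figure D4:**
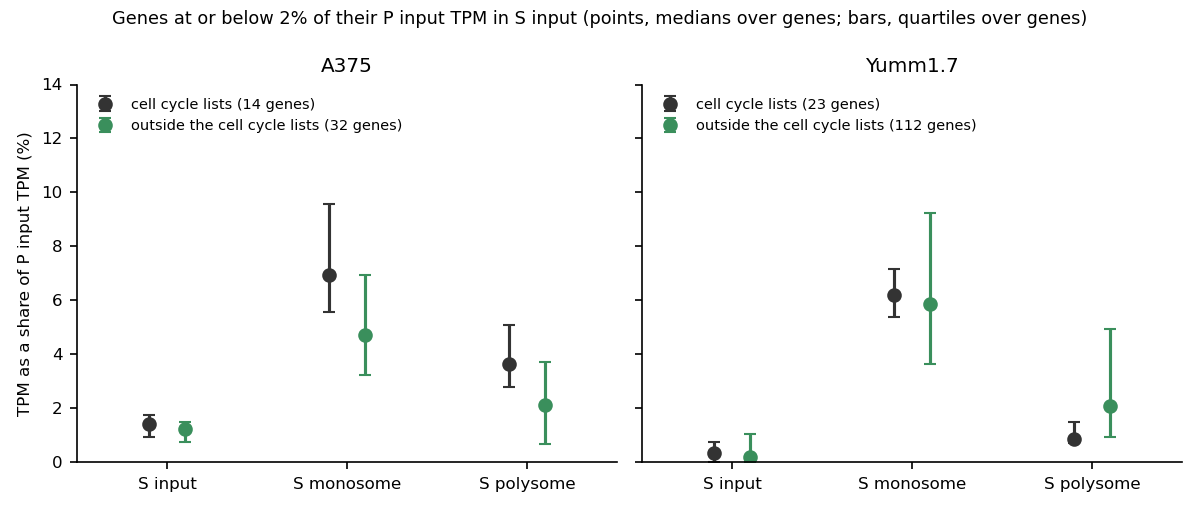
TPM in S input, monosome and polysome libraries as a percent of the TPM in P input (vertical axis) for genes at or below 2% of P in S input, split into cell cycle list genes (black) and other genes (green), with points for medians and bars for quartiles over genes. In both lines the S monosome medians (4.73% to 6.93%) lie above the S input medians (0.197% to 1.43%).

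The S minus P differences of the polysome-to-monosome ratio were less alike between the lines than those of input RNA (Pearson r 0.19, Spearman rho 0.12 across 8521 genes). Relative to the median gene, 192 genes had a higher ratio in both lines, where independent lists would share 107, and 137 a lower ratio in both, where independent lists would share 96.6. The highest in both were MT-TL1, MT-TW, MT-ND1, MT-TP, the ferritin heavy chain gene FTH1, MT-CO2, MT-TY, MT-ND4L, MT-CO3 and MT-CO1, which are mitochondrial transcripts apart from FTH1. The lowest in both were CCNB2, TACC3, NUF2, CDC20, UBE2C, PBK, TK1, PIMREG, TOP2A and HMGB2, which act in mitosis, DNA synthesis or chromatin. In Yumm1.7 S polysomes these genes had at most 3.97 TPM, with Nuf2 listed at 0 there and in S input and at 3.75 in S monosomes. A share of P RNA in S monosomes, left open below, would lower such ratios in both lines. The counts shared by both lines were not repeated with it subtracted. Across genes, the S minus P difference of the ratio was lower for longer coding sequences (Spearman rho -0.33 in A375 and -0.23 in Yumm1.7). Genes with the shortest and the longest coding sequences had medians of 0.28 and -0.42 in A375 and 0.28 and -0.32 in Yumm1.7. The random lists used for the list percentiles were matched on mean TPM and not on coding length.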

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

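Interferon-stimulated genes in input RNA moved in opposite directions in the 2 cell lines. The list had a median of 0.87 relative to the median gene in A375 (percentile 99.89 of matched random lists) and -1.04 in Yumm1.7 (percentile 0.15), as the only list beyond these bounds in opposite directions in the lines among those compared in input RNA and in the polysome-to-monosome ratio. The difference between the lines was not tested, since each state of each line has 1 library and the lists hold 18 and 25 genes tested, not all of them in both lines.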

How the results depend on the processing

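All results rest on 1 library per group, so leaving a library out was not possible. S was paired with P within each fraction to count genes past 2-fold in the same direction in all fractions, as given with the input results. No test on these pairs was made, and the fractions of a state are not replicates. With the pseudocount, the filter, the scaling and the genes in the TPM total varied, all lists that stood apart kept their direction, but sizes moved. This held for 41 of 144 list values with a pseudocount of 5, 26 of 142 with at least 10 TPM, 22 without a filter, 21 with a pseudocount of 0.1, 13 with median-of-ratios scaling and 7 of 134 without mitochondrial and ribosomal protein genes. Gene values moved in 49 of 101 cases with a pseudocount of 5, 30 with 0.1, 14 of 95 without those genes and 1 with median-of-ratios scaling. Settings fixed before the data were examined were joined later by centring on the median gene, by subtracting an estimated share of P RNA from S monosomes and by keeping only list members within 2-fold in input. The sign of the monosome-to-input comparison was turned after it was seen, because it runs opposite to the polysome-to-monosome ratio by construction.

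Genes past 2-fold in A375 input (4140) numbered 2519 with a pseudocount of 5, 2293 with a mean of at least 10 TPM and 6966 at 1.5-fold. In A375 P, polysome against monosome (7456), they numbered 4873 with at least 10 TPM and 4907 with median-of-ratios scaling. For the A375 difference of ratios (3044) they numbered 1485 with a pseudocount of 5, 1641 with at least 10 TPM, 6439 at 1.5-fold, 1050 against input and 352 as the share in polysomes. In Yumm1.7 input (5981) they numbered 3881 with a pseudocount of 5 and 3402 with at least 10 TPM. In Yumm1.7 P (5114) they numbered 2579 with median-of-ratios scaling, 3127 without mitochondrial and ribosomal protein genes and 2867 centred. In Yumm1.7 S (3344) they numbered 1606 with a pseudocount of 5, 2150 with at least 10 TPM and 5906 at 1.5-fold. For the Yumm1.7 difference of ratios (7293) they numbered 4435 with at least 10 TPM, 2915 with median-of-ratios scaling, 3133 centred, 3385 against input, 4315 as monosome over input and 2219 as the share in polysomes. The correlation between lines (0.48) was 0.25 in monosome libraries, and that of the ratio differences (0.19) was 0.31 with at least 10 TPM.

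The sign of these list medians turned. In monosome libraries it was 0.0396 for A375 proteasome subunits, 0.17 for A375 nuclear noncoding RNAs and 0.12 for Yumm1.7 tRNA synthetases, and in polysome libraries 0.0209 for Yumm1.7 heat shock proteins. Against input, A375 values were 0.18 for initiation factors, 0.36 for ribosome biogenesis, 0.35 for tRNA synthetases, 0.0430 for chromatin regulators, 0.14 for G1/S, 0.10 for G2/M and 0.75 for heat shock proteins. Those of Yumm1.7 were 0.0599 for G1/S, 0.14 for G2/M and 0.12 for the unfolded protein response. As monosome over input with the sign turned, Yumm1.7 mitochondrial ribosomal proteins were at -0.14 and oxidative phosphorylation at -0.20. With the P share subtracted, 14 of 72 list values moved and 1 turned (Yumm1.7 G1/S, 0.0138). The other lists that stood apart and moved are given with the result. With only list members within 2-fold in input, 18 of 62 list values moved and none turned, with the cell cycle lists giving no value (under 3 members left). The moved values of lists that stood apart are given with the number of members left in brackets, which was small for most. In A375 they were -0.0818 for ATF4 targets (7), -0.14 for ribosome biogenesis (26) and -0.21 for heat shock proteins (5). They were also -0.23 for tRNA synthetases (8), -0.38 for MAPK output genes (4) and 0.77 for snoRNA host genes (6). In Yumm1.7 they were -0.44 for the unfolded protein response (16), -0.52 for chromatin regulators (5), 1.32 for snoRNA host genes (3) and 3.10 for mitochondrially encoded mRNAs (4).

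Single genes whose sign turned were, in A375, NCL (1.20 in monosome libraries), AXL (0.14 in monosome libraries), NPM1 (0.12 in monosome libraries), MALAT1 (4.93 in monosome and 5.03 in polysome libraries), EEF1A1 (-0.60 in polysome libraries) and DUSP6 (ratio difference 0.82 with the P share subtracted). In Yumm1.7 they were Hspa5 (0.44 against input), Myc (0.60 against input and 1.19 with the P share subtracted) and Ccnd1 (0.74 with the P share subtracted).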

Other observations

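The ferritin mRNAs, whose translation is repressed through an iron-responsive element when iron is low, differed in the same way in both lines. FTH1 had 12266 TPM in monosomes and 632 in polysomes of A375 P and 4872 and 3072 in S, and Fth1 of Yumm1.7 had 14141 and 1305 in P and 3513 and 1715 in S. The light chain genes FTL (12113 and 337 in P, 10824 and 2236 in S) and Ftl1 (28228 and 2005 in P, 29414 and 8235 in S) did too. The light chain genes and the pairing with iron control were picked after the values were seen.

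In A375, the nuclear RNA MALAT1 was at 219 TPM in P input and at 11.8 and 11.1 in P monosomes and polysomes, but in S at 31.7 in input, 401 in monosomes and 341 in polysomes. The small Cajal body RNA SCARNA7 had 258 TPM in S monosomes against 0.715 in P monosomes.

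Setting polysomes against input was fixed before the data were examined. The other tests below, and the intervals over genes or list members that decide some of them, were chosen after the patterns were seen, with the bounds for the P ratio and coding length tests set before their values were computed.

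Genes that were nearly absent from S input were present in the S monosome library, with a monosome-to-input ratio above that of the median gene by 5.31-fold in A375 and 3.15-fold in Yumm1.7 for cell cycle list genes. These genes were chosen for low S input, which is also the denominator of this ratio, so the choice itself favours an excess. The ratio is of TPM + 1, which holds the excess down for genes near 0 TPM in S input. Its sizes are therefore not compared between the lines. The median levels of the cell cycle list genes in S polysomes stood above S input too. The genes chosen in the same way for low P input did not stand above P input in P monosomes. Genes outside these lists had an excess of 3.34-fold and 2.42-fold and a share of their P level 0.683 and 0.944 times that of cell cycle genes, but many of them also serve proliferation. Among protein-coding genes without a known role in proliferation, sorted by hand from known functions, the excess was 4.73-fold in A375 (11 genes, interval over genes 2.71 to 6.30). This lies above the bound of 2-fold set for a shift of proliferation mRNAs alone from polysomes to monosomes. It does not decide about such a shift, because the choice of genes by low S input favours an excess and the interval does not cover that. In Yumm1.7 the excess was 2.24-fold (50 genes, 1.75 to 3.10). It cannot decide about such a shift, because the interval includes the bound and TPM + 1 holds the excess down where S input is near 0. The share of the P level of these genes was 0.818 times that of cell cycle genes in Yumm1.7 (0.532 to 1.10), which fits a few percent of P RNA in the S monosome library. In A375 it was 0.695 times (0.407 to 1.38), where this cannot be told apart because the interval reaches below 0.5. Residual mRNA held in monosomes of S cells was not tested and stays open, so the lower polysome-to-monosome ratios of cell cycle genes, and of the other lists that shrank with an estimated share of P RNA subtracted, are not read here as a change of translation.

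Mitochondrially encoded mRNAs took a larger share of S polysome libraries. A higher amount of these mRNAs in S cells is not enough, since their S to P ratio in polysomes exceeded that in input by 2.31-fold in A375 and 5.46-fold in Yumm1.7. Carry-over of monosome RNA into the polysome fraction would raise snoRNA host RNAs equally. Their S polysome-to-monosome ratio was 0.148 of that of the mitochondrial mRNAs in A375 (0.0540 to 0.383 over list members), which speaks against it, while in Yumm1.7 (0.439, 0.0799 to 1.66) carry-over cannot be told apart from other causes. The higher share in polysomes was not confined to mRNAs. From P to S polysomes, mitochondrial ribosomal RNA went from 0.0565% to 1.20% of TPM in A375 and from 0.00942% to 0.114% in Yumm1.7. Mitochondrial transfer RNAs went from 0.306% to 2.25% and from 0.152% to 0.822%. Whether mitochondria or their ribosomes sedimented differently in S was not tested.

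Cytosolic ribosomal protein mRNAs of Yumm1.7 had a higher polysome-to-monosome ratio in S, with a median of 2.56 over 80 genes. A general loss of the difference between fractions is not enough, since the list stood at percentile 100 of random lists matched on the P ratio, whose medians had a midpoint of 1.33. Short coding sequences are not enough either (percentile 100 of random lists matched on coding length, for 79 genes with a length). Values of the S monosome library alone do not account for all of it (percentile 100 for polysomes against input, median 1.22). Random lists matched on mean TPM had a midpoint of 0.68 there, so much of that median was shared by other genes. As a share of TPM from P to S, ribosomal protein mRNAs went from 29.84% to 15.8% in monosomes and from 15.45% to 15.74% in polysomes. With 1 library per state, a difference between the 2 gradients in handling was not tested and stays open.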
